A study of Homo sapiens with 6 samples.

How the data were processed

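Total RNA of 6 KYSE150 samples (3 transfected with empty vector, 3 with circJPH1) was hybridised, 1 sample per array, with a single dye to Agilent expression arrays. Groups and replicate numbers come from the labels. The deposited files are scanner output from Agilent Feature Extraction, version 12.1.0.1 per the file headers and 10.7.1.1 per the submitters' processing notes. The processed signal used here is an intensity that, per the file headers, was background-subtracted and detrended, and it had not been normalized between arrays. The mean and local background intensity of each spot, as deposited, served 1 alternative. That alternative, normexp, added an offset of 50 to each signal, which shrinks the log2 fold changes of dim genes. Probe coordinates are those of the array design, on hg19 per the deposited files.

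Control spots and spots marked as outliers were left out, and spots of a probe were averaged, which gave 58201 probes. No probe was saturated. Because at most 45.0% of the probes on an array were well above background, each array's log2 processed signal was reduced by the 75th percentile taken over the 19042 probes well above background on all 6 arrays. Those percentiles were 831 and 730 on slide 1 (vector, circJPH1) and between 1584 and 1937 on slide 2. A probe was tested if well above background on all 3 arrays of at least 1 group, and each gene was represented by its brightest tested probe: 20459 probes passed, 15786 genes were tested, and 3635 genes had more than 1 tested probe. Of 12871 genes with a RefSeq accession, 12722 matched the RefSeq table of GRCh38.p14, used for names only; symbols are printed as in the files.

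Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) with Benjamini-Hochberg adjustment at 0.05. A set of 34 gene lists was fixed before the data were examined, and the 30 with at least 5 tested members were tested with camera (preset inter-gene correlation 0.01), beside an estimated correlation and fry. Genes were named by a rule fixed then as well: JPH1 probes, the 12 largest changes per direction among those passing with fully separated groups or else the 5 with the smallest raw p given as not passing (both among genes with a symbol, not LOC, clone or transcript names), the 4 members with the smallest raw p of each list described in detail, up to 3 circular and 3 long non-coding RNAs per direction by the same criteria, and HERC5, XRCC6, XRCC5, RELA and NFKB1. No long non-coding RNA passed the unblocked test, so none was named by that part of the rule. A bound is given for a probe not well above background on any array of a group: the other group's mean against the mean of, per array, the higher of the lowest signal well above background and the probe's own.

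Same-numbered arrays deviated together from their group means, with correlations across genes of 0.873, 0.798 and 0.722, so the numbers pair the samples by the criterion set beforehand. The pairing comes largely from the slides, as vector replicate 2 and circJPH1 replicate 3 correlated at 0.734. Slide was planned as a block in case a slide held over 1 array. The fit was tested on simulated data with the real means and slide effects over 15770 genes, 200 of them changed. Noise was drawn independently for each gene, from the variance that eBayes gave in the slide-blocked fit. Without a block the fit recovered 30.0% of 100 genes changed by a log2 of 1 and 75.0% of 100 changed by 2, and with the slide block 95.0% and 99.0%, with 9 false calls. These shares may not carry over to the real data. Correlation between genes was not simulated, and only 21 real genes reached 2-fold with an unadjusted p under 0.05. Alternatives covered normalization, background correction, filtering, the variance model, blocks, probes per gene, thresholds and leaving out each replicate, in which the tested genes and the scaling were kept. Leaving out 1 array unbalances the groups over the slides, so without a block the slide difference can enter those values. Further alternatives added after the data were seen are named as such in the closing section. The value of 1 member of the interferon-stimulated list is not reported here.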

Results

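RNA of KYSE150 cells, a line established from a human esophageal squamous cell carcinoma, was measured on 6 single-colour expression arrays. In 3 samples the cells had been transfected with an empty vector, and in 3 with a construct that overexpresses circJPH1, a circular RNA made from the JPH1 gene. The labels do not say whether the replicates were separate cultures. The p-values of single genes and of fry therefore measure only the spread between these samples, which may be technical. The number of arrays limits their precision. Camera with the preset correlation compares list members with the other genes, so its p-values rest on the spread across genes, not between arrays. Between 33.6% and 45.0% of the 58201 non-control probes were well above background on an array. After filtering, 15786 genes were tested, each through 1 probe, and 11325 of them were annotated to a protein-coding transcript. The arrays lay on 2 slides, each with its own scan: replicate 1 of both groups on slide 1, which was dimmer, and replicates 2 and 3 of both groups on slide 2. The first principal component, with 82.6% of the variance, separated the slides. Differences between the groups are therefore given over all 6 arrays, with slide as a block, and within each slide. Slide 1 holds 1 array per group, which gives a value without a test.

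**Figure D1:**
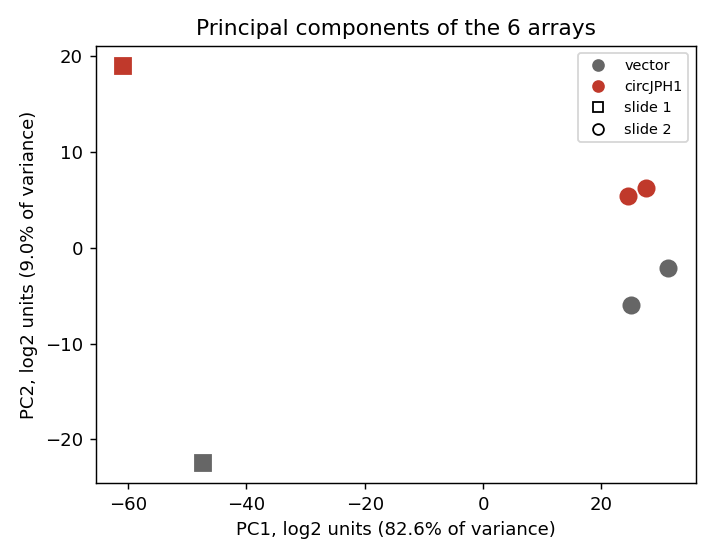
The 6 arrays are plotted on the first principal component (82.6% of the variance) against the second (9.03%), in log2 units, over the tested genes. Squares (slide 1) and circles (slide 2) lie apart on the first axis, and within each slide the circJPH1 arrays (red) lie above the vector arrays (grey) on the second.

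The array carried no probe annotated as a circular RNA, so circJPH1 itself was not measured. Its host gene, JPH1, encodes a junctophilin, a protein that ties the cell membrane to internal calcium stores. JPH1 had 1 probe (NM_020647, hg19 chromosome 8, 75147000 to 75147059), which was not well above background on any of the 6 arrays. Its normalized log2 signal was -8.81 ± 0.78 (SD, n = 3) in vector and -8.77 ± 0.89 (SD, n = 3) in circJPH1 arrays, and no fold change is given. Which part of JPH1 is circularised is not given in the sources used here, so this probe does not check the overexpression.

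The comparison of circJPH1 with empty vector asks which linear RNAs differ when the circular RNA is overexpressed. Of 37 tested interferon-stimulated genes, which encode antiviral effectors and RNA sensors, 32 were higher and 2 lower in circJPH1 on both slides, and no member passed over all genes without a block. The list passed camera's preset-correlation test (adjusted p = 1.3e-33) but not with an estimated correlation (adjusted p = 0.123). The cytokine genes IL6, IL1A and CXCL2 were also higher in circJPH1 on both slides. HERC5, the ligase that attaches ISG15 to newly made proteins, was 5.23-fold higher (log2 2.39, SE 0.12 with the slide block, n = 3 per group, hg19 chromosome 4, 89426889 to 89426948), with a log2 difference of 2.45 on slide 1 and 2.36 on slide 2. The slide 1 value is not exact, because HERC5 was not well above background on that slide's vector array. The lowest signal well above background there was -5.78, and HERC5 was at -4.57 on circJPH1 replicate 1. IFIT3 was 3.66-fold, IFIT1 2.95-fold, IFI44 2.89-fold and ISG15, a ubiquitin-like protein, 2.08-fold higher. For each of these 5 genes all 3 circJPH1 arrays exceeded all 3 vector arrays, which their choice by the smallest raw p favours. Groups of 3 exchangeable arrays separate, in either direction, for 10% of genes by chance, but these arrays share slides: the groups separated for 6.46% of genes, against 1.89% to 2.45% in the 5 other slide-balanced splits. HERC5 was well above background on 2 of 3 vector arrays and on all 3 circJPH1 arrays. Its log2 fold change was 0.85 under normexp, where the added offset of 50 shrinks differences of dim genes. How much of that drop came from the background correction itself was not tested. The study probably took up HERC5 from these samples, so its place here is not independent evidence.

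No single gene passed the planned test without a block: limma called 0 of 15786 genes at a Benjamini-Hochberg adjusted p under 0.05, and the lowest adjusted p was 0.196, for IFIT3. At an unadjusted p under 0.05, 247 genes were higher and 50 lower in circJPH1. With the replicate number as a block limma also called 0 genes (lowest adjusted p 0.0768), with 1396 genes higher and 828 lower at an unadjusted p under 0.05. With slide as a block, a setting listed before the data were examined, 28 genes rose and 1 fell. At an unadjusted p under 0.05 in that fit, 1570 were higher and 970 lower. With trend and robust variance added, 269 rose and 67 fell. All 29 differed in the same direction on both slides, but the test itself favours such genes, as disagreement between slides adds to its residual. Over all tested genes the differences on slide 1 and slide 2 correlated at 0.291. The median residual SD was 0.259 (log2) without the block and 0.0773 with it. Within slide 2 (2 arrays against 2), 9 of the same 15786 genes passed, and 0 of 19051 genes passed when the filter was set on those 4 arrays alone (1296 higher and 703 lower at an unadjusted p under 0.05). Fewer calls were left whichever array was left out. Without circJPH1 replicate 2, circJPH1 replicate 3 or vector replicate 2 none was left, and without vector replicate 3 there were 3. Without vector replicate 1 or circJPH1 replicate 1 there were 9. Both of these are the fit within slide 2, as the block absorbs the remaining array of slide 1. Each omission also leaves fewer arrays to estimate the spread, so these losses do not show that a single array drove the calls.

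Of the 29 genes that passed with the slide block, 11 belong to the interferon-stimulated list and 3 to the NF-kB target list. Genes outside the naming rule in this paragraph were chosen after their values were seen. DHX58, an RNA sensor, rose 4.99-fold, OASL 4.13-fold, RSAD2, the antiviral enzyme viperin, 4.01-fold, IFIT2 3.57-fold and DDX60 2.68-fold. Under normexp the log2 fold change of DHX58 was 1.25 in place of 2.32, and that of RSAD2 1.42 in place of 2.00. CCL5, a chemokine, rose 3.97-fold (adjusted p = 0.0204 in limma with the slide block). DDX58, which encodes the RNA sensor RIG-I, rose by 0.51 on the log2 scale, with a second probe of the gene at a vector mean of -4.41 and a circJPH1 mean of -3.69. Among cytokines, IL6 rose 1.84-fold, IL1A 1.83-fold and CXCL2 1.52-fold. CHAC1, a glutathione-degrading enzyme induced by amino acid stress, rose by 0.65 (log2) and FGFBP3 by 0.61 (0.37 under normexp). Of the 29, 9 were non-coding or unannotated, and among them the probe A_33_P3298980 (hg19 chromosome 7, 138734016 to 138734075) rose 2.82-fold. The gene that fell was KRT15, a keratin of basal squamous cells, with a log2 fold change of -0.58 (SE 0.05, adjusted p = 0.0496).

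**Figure D2:**
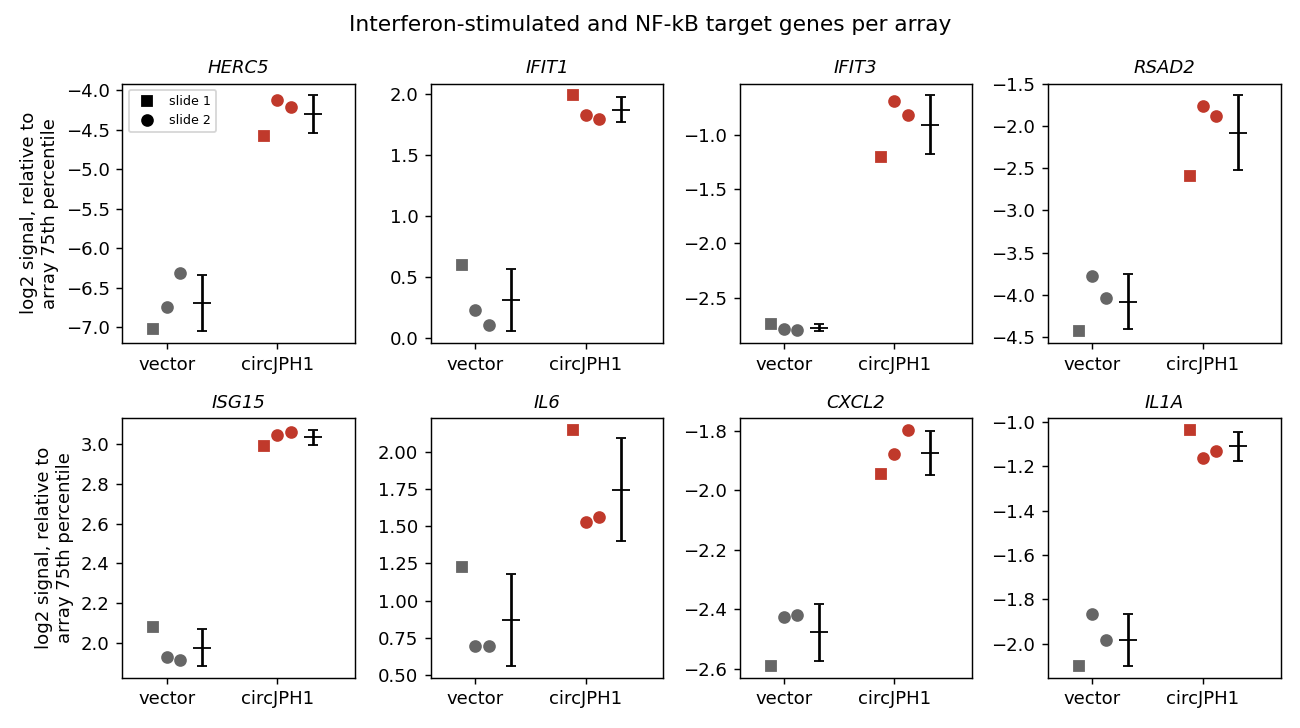
Normalized log2 signal of 8 genes on each array (vertical axis, relative to the array's 75th percentile), with squares for slide 1, circles for slide 2, and a bar with whiskers for the mean and SD of the 3 arrays of a group. All circJPH1 arrays lie above all vector arrays, by a mean log2 difference between 0.60 for CXCL2 and 2.39 for HERC5, whose vector replicate 1 was not well above background.

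As a group, the interferon-stimulated genes shifted up: the median log2 fold change of the 37 tested members was 0.27 (0.24 on slide 1, 0.45 on slide 2), and 32 were higher in circJPH1 on both slides. Camera with a preset inter-gene correlation gave an adjusted p of 1.3e-33, and 5.1e-20 with the slide block, but the call was lost with an estimated correlation (adjusted p = 0.123, and 0.34 with the slide block). Fry gave an adjusted p of 0.0395, and 0.0103 with the slide block. Over all genes 0 members rose without the block. Adjusted over the list alone, 13 rose and 0 fell without the block, and 23 rose and 0 fell with it. Over all genes, with the block, 11 rose and 26 did not pass. The size varied between members, and USP18 at 0.05 and TRIM25 at -0.03 did not pass, both named after their values were seen. Members with the smallest raw p were IFIT3, HERC5, ISG15 and IFIT1.

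The NF-kB target genes, which encode cytokines, chemokines and feedback inhibitors, shifted up as well. The median log2 fold change of 31 tested members was 0.27 (0.30 on slide 1, 0.29 on slide 2), with 24 higher on both slides. The adjusted p was 2.9e-16 with camera's preset correlation, 0.0202 with an estimated one and 0.00931 with fry. With the slide block these were 2.1e-13, 0.335 and 0.0103, so the call with an estimated correlation was lost there. The estimated correlation was 0.00107 without the block and 0.0483 with it, against the preset 0.01. For the interferon-stimulated list the estimates were 0.216 and 0.155. The estimated form also rests on the few residual degrees of freedom of the arrays, so its larger p-values do not reflect correlation alone. Over all genes, 0 members passed without the block and 3 rose with it (IL6, IL1A and CXCL2), while 28 did not pass. Adjusted over the list alone, 3 rose without the block and 18 with it. BIRC3, an apoptosis inhibitor, had a log2 fold change of 0.52 (SE 0.07 with the block) and did not pass over all genes (adjusted p = 0.108). The signalling components themselves did not pass as a group: the 20 members of the NF-kB pathway list had a median of 0.03 (adjusted p = 0.47). RELA had a log2 fold change of -0.01 (SE 0.05 with the slide block) and NFKB1 0.01 (SE 0.06), while RELB was at 0.30, NFKB2 at 0.24, MAP3K14 at 0.18 and TAB1 at -0.20, none passing. The pathway and target lists share 6 tested genes.

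The heat shock list, of chaperones, was shifted down with the preset correlation only, with a median of -0.07 over 21 members (-0.11 on slide 1, -0.05 on slide 2, adjusted p = 0.00389, and 0.000721 with the slide block). With an estimated correlation the adjusted p was 0.748, and with fry 0.908. Without a block, the call was also lost without vector replicate 2 (adjusted p = 0.0975), vector replicate 3 (0.122) or circJPH1 replicate 1 (0.848), where the median was 0.04. It was kept without vector replicate 1 (median -0.22), circJPH1 replicate 2 (-0.19) or circJPH1 replicate 3 (-0.18). Leaving out 1 array unbalances the groups over the slides, so the slide difference can enter these values. Adjusted over the list alone, 0 members fell without the block and 5 with it. Over all genes no member passed, with HSP90AB1 at -0.31, DNAJB1 at -0.34, HSPA8 at -0.48 and HSPA1B at -0.47.

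With the slide block, 3 further lists passed with the preset correlation and none of them with an estimated one. Proteases and invasion genes had a median of 0.09 (0.12 on slide 1, 0.07 on slide 2, adjusted p = 0.125 without and 0.00227 with the block, 0.524 with an estimated correlation and the block), with ADAM19 at 0.32, ADAM8 at 0.31 and MMP28 at 0.22, none passing over all genes. Without a block, the median of this list was -0.02 without circJPH1 replicate 1 (adjusted p = 0.92), 0.28 without vector replicate 1 (0.0114) and 0.20 without circJPH1 replicate 2 (0.0188). These 3 values lie outside the medians of the 2 slides. With 1 array left out the groups are unbalanced over the slides, so the slide difference can enter them. A further named member, ADAMTS1, had a log2 fold change of 5.17 from a single spot on circJPH1 replicate 1, with a difference of 0.01 on slide 2. The gene's second probe was not well above background on either array of slide 1, and was so on the 4 arrays of slide 2. Antigen presentation genes had a median of 0.04 (0.05 and 0.09 on slides 1 and 2, adjusted p = 0.386 without, 0.0325 with the block and 0.529 with an estimated correlation and the block), with NLRC5 at 0.29, ERAP2 at 0.26, ERAP1 at 0.22 and PSMB9 at 0.20. Basal squamous lineage genes had a median of -0.10 (-0.10 and -0.02 on slides 1 and 2, adjusted p = 0.0607 without, 0.0348 with the block and 0.529 with an estimated correlation and the block). Without a block, the basal squamous median was -0.17 without circJPH1 replicate 1 (0.184), -0.03 without vector replicate 1 (0.378) and -0.12 without vector replicate 2 (0.0394). Beside KRT15 they included NGFR at -0.18, PAX9 at -0.18 and EGFR at 0.12, which did not pass.

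**Figure D3:**
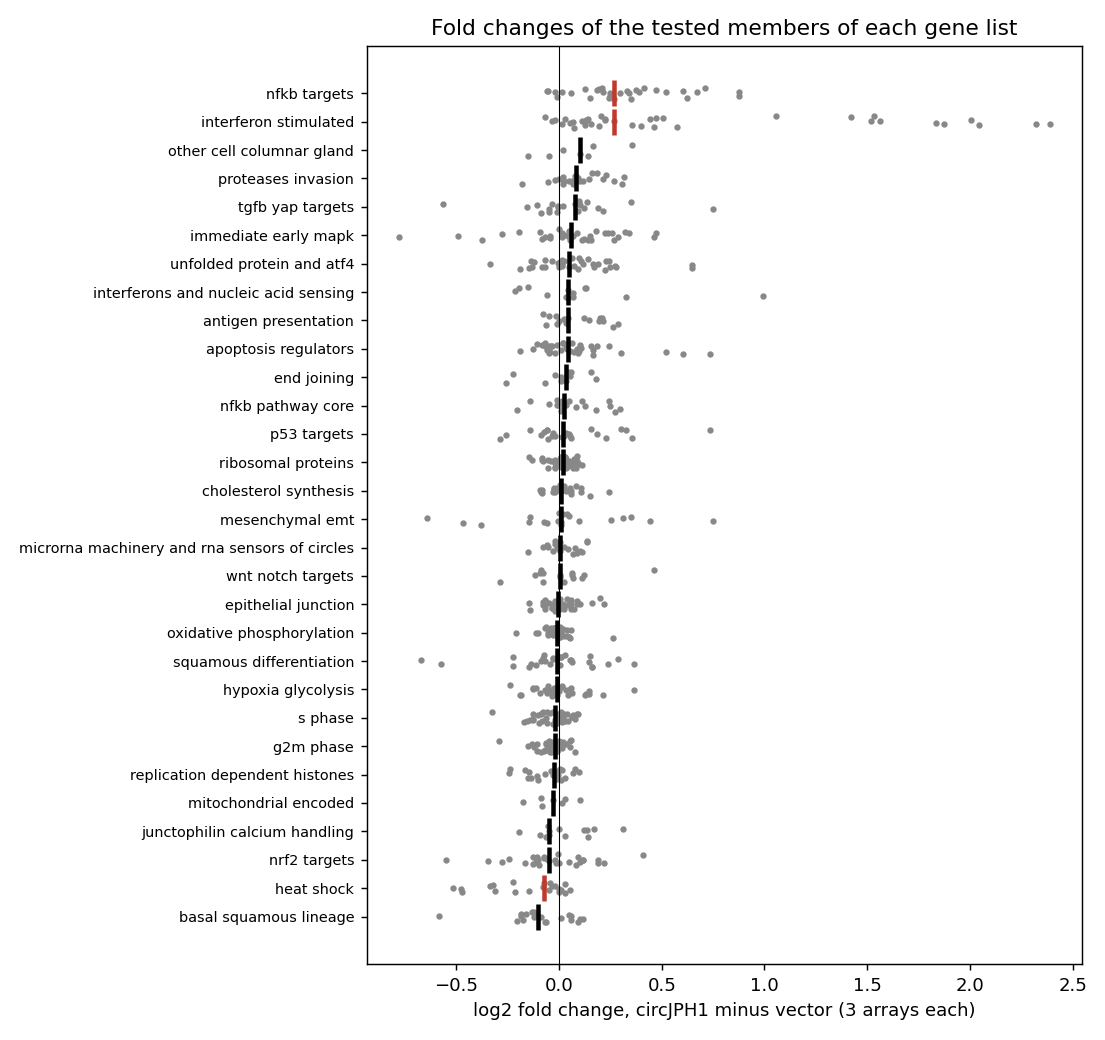
Each row is a gene list and each grey point the log2 fold change of a tested member, circJPH1 minus vector (3 arrays each, horizontal axis), with a bar at the list's median, red where camera's preset-correlation test passed without a block. The interferon-stimulated and NF-kB target lists have medians of 0.27. The ADAMTS1 value of 5.17 in the protease list is outside the plotted range.

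DNA end joining genes, the repair pathway in which XRCC6 and XRCC5 bind broken ends, did not pass as a group (13 members, median 0.04, adjusted p = 0.892). XRCC6 had a log2 fold change of 0.04 (SE 0.04 with the slide block, adjusted p = 0.723) and XRCC5 -0.26 (SE 0.07, adjusted p = 0.211). ATM was at 0.18, POLM at 0.16, PAXX at 0.05 and TP53BP1 at -0.22. With the mean of the tested probes of a gene in place of the brightest, ATM was at -0.16 and POLM at 0.09. Mesenchymal genes had a median of 0.01 over 20 members (adjusted p = 0.791) and went both ways, with CCN2 at 0.75, INHBA at 0.44, S100A4 at 0.26 and VIM at -0.38. Squamous differentiation genes had a median of -0.01 over 28 members (adjusted p = 0.47), with KRT16 at -0.67, KLK5 at -0.23, FLG at -0.22 and KLF4 at 0.36. Immediate early and MAPK-responsive genes had a median of 0.06 over 34 members (adjusted p = 0.386), with FOSB at -0.78, FOS at -0.49, DUSP6 at 0.47 and AREG at 0.26. None of these genes passed over all genes. Adjusted over the list alone, with the slide block, 1 end joining gene fell, 4 mesenchymal genes rose and 1 fell, 2 squamous differentiation genes rose and 2 fell, and 8 immediate early genes rose and 3 fell. Adjusted in the same way, 5 protease genes and 0 antigen presentation genes rose, 1 basal squamous gene fell, and 2 NF-kB pathway genes rose. The 5 lower genes with a symbol and the smallest raw p, none of which passed, were FOSB, ID2 at -0.57, SNORD56 at -0.49, RAB3A at -0.42 and SPPL2B at -0.42. All were smaller under normexp, in the same order -0.46, -0.11, -0.23, -0.15 and -0.13.

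Cell cycle genes did not pass in the planned test. The median was -0.02 for 41 S phase genes (adjusted p = 0.249) and -0.02 for 41 G2 and M phase genes (adjusted p = 0.119). The G2 and M list passed with the preset correlation within slide 2 (median -0.05, adjusted p = 0.000967), while its slide 1 median was 0.02. It also passed with normexp background (adjusted p = 0.00339), with no filter on dim probes (0.00593), and without vector replicate 2 (0.00989) or circJPH1 replicate 1 (0.000434). Replication-dependent histones had a median of -0.02 (adjusted p = 0.386), which was -0.30 without vector replicate 1 (0.00421) and -0.18 without circJPH1 replicate 3 (0.0466), and they passed with no filter on dim probes (0.0458). Apoptosis regulators had a median of 0.04 (0.157), p53 targets 0.02 (0.519), unfolded protein and ATF4 targets 0.05 (0.347), NRF2 targets -0.05 (0.386), hypoxia and glycolysis genes -0.01 (0.519), cholesterol synthesis 0.01 (0.791), TGF-beta and YAP targets 0.08 (0.791) and Wnt and Notch targets 0.01 (0.892, where the test pointed down). Oxidative phosphorylation genes had a median of -0.01 (0.47), mitochondrially encoded genes -0.03 (0.558), ribosomal proteins 0.02 (0.791), epithelial junction genes -0.002 (0.791, with a mean of 0.01), microRNA machinery and RNA-binding sensors of circles 0.01 (0.839), and junctophilin and calcium-handling genes -0.05 (0.791, where the mean was 0.02 and the test pointed up). The number in each parenthesis is the adjusted p of camera with the preset correlation. Apoptosis regulators passed in that test within slide 2 (median 0.06, adjusted p = 0.0042) and with normexp background (0.00339), ribosomal proteins passed without vector replicate 2 (median 0.10, 0.0466) or circJPH1 replicate 1 (median 0.14, 0.00528), and p53 targets passed in fry with the slide block (0.0212). Where 1 array was left out, there was no block and the groups were unbalanced over the slides. The slide difference can therefore enter those values of the G2 and M, histone and ribosomal protein lists. Adjusted over the list alone, with the slide block, 9 unfolded protein and ATF4 targets rose, and 1 member passed over all genes. In the same way 6 p53 targets rose and 1 fell, 3 apoptosis regulators rose, and 2 TGF-beta and YAP targets rose and 1 fell. The hypoxia, junctophilin and Wnt and Notch lists each had 1 gene that rose, and the other lists of this paragraph had 0.

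Markers of other cell types did not pass. Columnar and glandular markers had a median of 0.10 over 7 tested members (adjusted p = 0.47). Of the immune, fibroblast and kidney or neural markers 4 each were tested and of the endothelial markers none, too few for a list test. The immune markers tested were CSF1R at -0.27, CD14 at 0.15, CD79A at -0.11 and FCER1G at 0.03.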

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

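The alternatives were planned before the data were examined, except the slide 2 arrays alone, every variation of the slide-blocked count, and the slide block combined with an estimated correlation or fry, which were chosen after seeing the data. The cause of the changes below was not tested. The count of changed genes was 0 without a block and in the settings listed beforehand except the slide block (29 genes) and the threshold of an unadjusted p under 0.05 with at least 2-fold (21 genes, all higher, 14 of them among the 29), and it was 0 with the replicate block and 9 with slide 2 arrays only (0 with the filter set on those arrays). The slide-blocked count of 29 varied widely: 17 with quantile normalization (all 17 among the 29), 136 with normexp background (22 shared), 0 with no filter on dim probes, 44 with probes well above background on all 6 arrays (23 shared), 336 with trend and robust variance (27 shared), and 0 to 9 when 1 array was left out. DHX58 and RSAD2 passed in 9 of those 13 variations and HERC5 in 6. No gene could pass in all 13, since some of them gave 0 calls. HERC5 was not tested with probes well above background on all 6 arrays. With the slide block, leaving out vector replicate 1 or circJPH1 replicate 1 gives the same fit, that of slide 2 arrays only. These variations are therefore not separate evidence. The number of shifted lists was 3, against 7 with normexp background, 8 with no filter on dim probes, 6 with the replicate block, 6 with the slide block, 7 with slide 2 arrays only, 7 with those arrays and their own filter, 4 with probes well above background on all 6 arrays (basal squamous added), 2 with fry (heat shock lost), 1 with an estimated correlation, 0 with the slide block and an estimated correlation, 4 with the slide block and fry (the interferon-stimulated, NF-kB target, protease and p53 target lists), and 2 to 5 when 1 array was left out (2 without vector replicate 3, 5 without vector replicate 1 or vector replicate 2). The replicate block added the antigen presentation, basal squamous and protease lists, as the slide block did. Normexp added the apoptosis, basal squamous, S phase and G2 and M lists, and testing without a filter the basal squamous, S phase, G2 and M, NRF2 and histone lists. Slide 2 arrays only added the antigen presentation, apoptosis, G2 and M and protease lists, with either filter. Lists added when 1 array was left out were the protease, histone, basal squamous, G2 and M and ribosomal protein lists. Those tests had no block and groups unbalanced over the slides, so the slide difference can enter them. The interferon-stimulated and NF-kB target lists had positive medians in all settings, from 0.20 to 0.45 and from 0.24 to 0.38. The fit without a block called 0 genes, so no named gene's call could be reversed. Of 1302 comparisons of 77 named genes with an alternative, 38 gained a call, a count fixed by naming all 29 slide-blocked calls. Another 24, in 8 genes, differed in sign without a call. The median log2 fold change of all genes was 0.004, and -0.005, 0.022 and -0.023 under quantile normalization, normexp and the percentile over all probes. Changes in circular RNA and in JPH1 could not be recomputed, as no circular RNA probe was present and the JPH1 probe was below background. With 33.6% to 45.0% of probes well above background, dim genes are the ones most limited by signal.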

Other observations

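Tests on slide difference, dim genes, the transfected nucleic acid, brightness of non-coding transcripts and single bright spots were chosen after the result was seen. Interferon genes themselves were near the detection limit. IFNL1, a type III interferon chosen after its values were seen, was not well above background on any vector array and was so on 2 of 3 circJPH1 arrays. By the bound described above it was 1.96-fold higher. That bound is not strict, because it uses the value on circJPH1 replicate 1 (-5.69), below the lowest signal well above background there (-5.58). IFNL1 was outside the filter, and with no filter and the slide block it did not pass (limma, adjusted p = 0.248). IFNL2 had a log2 fold change of 0.99 (0.84 on slide 1, 1.07 on slide 2, 0.43 under normexp, adjusted p = 0.403 in limma, and 0.0588 with the slide block), so it did not pass. The probes of IFNB1, IFNL3, CXCL10 and CXCL11 were not well above background on any array. The list of interferons and nucleic acid sensing genes had a median of 0.05 over 13 members (camera, adjusted p = 0.409), with STING1 at 0.33, TLR3 at 0.13 and MAVS at -0.19.

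The higher level of interferon-stimulated and NF-kB target genes was weighed against 3 explanations. A slide difference shared by both groups cancels by design, because each slide holds as many circJPH1 as vector arrays. A rise confined to 1 slide is argued against, since 82.4% of the 68 tested members of both lists were higher in circJPH1 on both slides. A signal-dependent shift of dim genes is argued against, since the interferon list's median of 0.27 lay at percentile 100 of 10000 random lists matched on brightness, whose 99th percentile was 0.05. A response to the transfected nucleic acid itself cannot be told apart from an effect of circJPH1, because 0 arms with another circular RNA or construct are among the samples, and the biological difference that the design names also stays open. With the slide block, 1 of 6 slide-balanced splits of the arrays gave as many calls as the real 29, the highest other split giving 0, and 6 of the 10 splits of the 6 arrays shifted as many lists as the real 3, the highest other giving 4. Those 6 were 3 of the 6 slide-balanced splits and 3 of the 4 that put both slide 1 arrays in 1 group. Over the slide-balanced splits the absolute median of the interferon list was 0.27 in the real split and at most 0.18 in the others. Without a block all 10 splits gave the real count of 0 genes (highest other 0). In each case the splits are too few for a share under 0.05. For the list count that is not the only limit: other splits reached the real 3, so this number does not set the real grouping apart.

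Non-coding and unannotated transcripts were slightly higher than coding ones in circJPH1, with a difference of medians of 0.05 (log2) on slide 1 and 0.03 on slide 2. Matching on brightness left 0.0684 and 0.0348. In the same measure vector replicates 2 and 3, which share slide 2, differed by 0.0442, and circJPH1 replicates 2 and 3 by 6.5e-05, a comparison fixed before its value was seen. A signal-dependent shift of dim transcripts and array-to-array variation unrelated to the groups both stay open, because the slide 2 difference is within that spread and the slide 1 difference, from 1 array per group, is above it. No biological explanation was tested.

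Single spots were far brighter on 1 array than on the other 5: 65 probes exceeded them by over 3 (log2), 53 of them on slide 1, and 4 of the 65 stood for a tested gene. The ADAMTS1 spot on circJPH1 replicate 1 exceeded the others by 14.4, and more ADAMTS1 RNA on that array is argued against, since the gene's second probe differed there from its median on the other 5 arrays by -1.60. It was not well above background on either slide 1 array, and on circJPH1 replicate 1 the lowest signal well above background (-5.58) lay above the probe's level on the other 5, so the lack of detection is expected with no change. It leaves room for a rise of 0.518, but not for one near 14.4. For the other spots, whether more RNA of the gene was the source stays open. Of 34 other probes of these genes, 16 were higher by over 1 on the same array, but this form of the test is void on slide 1, where 73.2% and 81.6% of the 30682 probes not well above background on any array were higher by that much. The test was run in 4 forms, and the others gave 1 of 9 probes (only probes well above background on at least 3 arrays), and, for the 12 spots exceeding by over 5, 2 of 6 and 1 of 4 probes.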
